A study of Mus musculus with 12 samples.

How the data were processed

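RNA was measured by sequencing in 12 spleen libraries of mice, 3 in each of 4 groups: untreated control, alginate oligosaccharides (AOS, short chains made from the seaweed polysaccharide alginate) at 10 mg/kg for 5 weeks, the alkylating drug busulfan at 40 mg/kg given once, and busulfan followed by AOS at the same doses. The groups were taken from the submitters' labels and design text. The sample code of the busulfan libraries differs by a letter from the code in the design text and was read as busulfan without AOS. The labels give the strain as IRC and do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical.

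The table used here holds expected counts per gene, which the authors deposited under column names that call them read counts, and 75.7% of the values are exactly whole numbers. The same table holds a normalised expression value per gene and library, which was read as FPKM as deposited by the authors, because the ratio of the count to this value followed the library totals to within 0.39% over 1226 genes with at least 2000 counts, while a TPM scale would have been off by up to 7.65%. The genome build was mm10 per the submitters' processing notes. The aligner, the counting program, the gene annotation, the library type and its strandedness are not given in the sources used here. Reads of genes that overlap, of antisense partners and of near-identical copies may therefore have been split or shared in ways that cannot be traced, which applies to the haemoglobin genes, Hspa1a and Hspa1b, the amylases and trypsins, and the genes of the major histocompatibility complex.

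The table has 19376 rows, of which 18362 carry an Entrez gene number and 1014 carry an identifier starting with BGIG. Of the Entrez numbers, 18233 were matched in a RefSeq table of assembly GRCm38.p6, the assembly behind mm10, which gave the coordinates, printed 1-based, while the symbols are those of the table. Rows with a BGIG identifier held 2.72% to 3.13% of the counts of a library, stayed in the library totals and the gene test, and are not named. A further 8 columns with group averages by the authors were not used here, and 40 rows were 0 in every library. Library totals ran from 15051300 to 16241884 counts, so that 3 counts, the upper limit a count of 0 allows, correspond to 0.185 to 0.199 CPM. Such limits cover counting error only. Pairs of libraries of 1 group differed by 15.9 to 72.7 times the sampling noise (chi-square per degree of freedom, 12 pairs, genes with at least 20 counts summed), so no library was a copy of another.

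Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (15079 genes), libraries were scaled by TMM (factors 0.965 to 1.04), and 1 model with a mean per group was fitted to all 12 libraries with glmQLFit, leaving 8 residual degrees of freedom with 2.97 prior degrees of freedom and a common biological coefficient of variation of 18.9%. Contrasts were tested two-sided with glmQLFTest and adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM on TMM-scaled library sizes, given as mean ± SD of 3 libraries. Other software was limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

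The comparisons were busulfan against control, busulfan with AOS against AOS, AOS against control, busulfan with AOS against busulfan, busulfan with AOS against control, each treatment averaged over the other, and the interaction. In addition, 39 gene lists with 506 genes (spleen cell types, pathways, other tissues, RNA quality and handling) were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 37 lists with measured members. Beside it stand camera with an estimated correlation, fry, and the number of members called over all genes and adjusted over the list alone. A list level is the median over members of log2 CPM minus its mean over all libraries, while the covariates are means over members. Intervals of a difference of list levels are 95% intervals from the pooled spread of the 4 groups. The lists of immunoglobulin constant regions and of mitochondrially encoded genes had no member in the table and are not analysed here.

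For each comparison of 2 groups the text names genes by a rule. These are the 10 genes of each direction with the largest log2 fold change among called genes whose 3 libraries of a group all lay above the 3 of the other and whose mean was at least 5 CPM in the higher group, and of each list that passed its test the 4 members with the smallest p. Where fewer than 5 genes were called, the 5 of each direction with the smallest p were taken. Some genes that meet this rule are not reported here. Predicted genes, pseudogenes, small RNAs and receptor gene segments were left out. Groups, comparisons, tests, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Alternatives added afterwards were the pancreatic acinar or heat shock list level as a covariate, limma-trend on log2(FPKM + 1) of 13115 genes with at least 1 FPKM in 3 libraries, removal of the 2 libraries with most transcripts of another tissue, and the replicate block for the agreement and reversal of comparisons. Genes named outside the rule are marked as chosen after their values were seen.

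The gene test was tested on simulated data drawn from the means and totals of the real libraries, each gene independently of the others. Only genes with a mean of at least 5 CPM were changed, so the recovery holds for such genes. For busulfan against control (14917 genes) the gene test recovered 81% of 100 genes changed by a log2 of 1 and 96% of 100 changed by a log2 of 2, with 7 false calls. For busulfan with AOS against busulfan (14914 genes) it recovered 89% and 96%, with 8 false calls. In both simulations the 1 list raised on purpose passed camera and 0 other lists did. In the real libraries, splits other than the groups called up to 19 lists in comparisons of 2 groups. The simulations therefore do not measure false list calls in the real libraries. The correlation of fold changes between comparisons was set beside 20 simulations without any effect. Alternatives chosen beforehand were DESeq2 size factors, DESeq2's Wald test, no filter and a stricter filter (5 CPM in 3 libraries), only the libraries compared, the replicate number as a block, an added threshold of an absolute log2 fold change of 1, and leaving out each library in turn.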

Results

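RNA was sequenced from mouse spleen in 12 libraries, 3 each from untreated controls, mice given alginate oligosaccharides (AOS), mice given the alkylating drug busulfan, and mice given busulfan and then AOS. Library totals ran from 15051300 to 16241884 counts. The 4 groups form a 2 × 2 design that asks what each treatment does to the spleen, and whether AOS alters the state after busulfan. Haemoglobin transcripts, the product of red cell precursors, took 6.52 ± 0.944% of counts in controls, 6.98 ± 0.377% with AOS, 8.69 ± 0.289% with busulfan and 8.01 ± 1.90% with both. Transcripts of 20 digestive enzyme genes of the exocrine pancreas took 0.292%, 4.42% and 0.520% of counts in the AOS libraries and 0.00192% to 0.241% in the other 9. The fat cell hormone gene Adipoq stood at 28.9 CPM in control 1, against 0.310 to 3.63 CPM in the other 11.

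**Figure D1:**
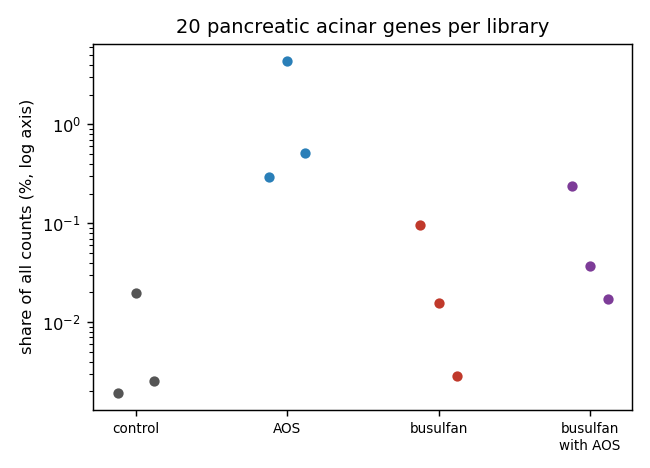
Share of all counts taken by 20 pancreatic acinar genes (vertical axis, percent, log scale) in each library (points) of the 4 groups (horizontal axis). The 3 AOS libraries, at 0.292% to 4.42%, lie above the other 9.

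Busulfan against control asks what the drug left in the spleen without AOS. Prg2, the major basic protein of eosinophil granules, rose from 1.57 ± 0.411 to 22.7 ± 13.6 CPM (n = 3 each; log2 fold change 3.85 ± 0.52 SE, edgeR adjusted p = 0.0248). Epx, eosinophil peroxidase, rose from 0.553 ± 0.132 to 6.97 ± 4.55 CPM. Retnlg, a secreted resistin-like protein of granulocytes, rose from 7.25 ± 1.77 to 75.0 ± 48.9 CPM, Ly6g, the surface marker of neutrophils, from 1.51 ± 0.423 to 14.1 ± 10.5 CPM, and Mmp8, the neutrophil collagenase, from 10.5 ± 1.84 to 84.4 ± 65.3 CPM. The p53 target Eda2r, a receptor of the tumour necrosis factor family (Entrez 245527, protein coding, GRCm38 chromosome X, 97333837 to 97377234), rose from 1.45 ± 0.304 to 6.36 ± 0.501 CPM (log2 2.13 ± 0.25 SE, edgeR adjusted p = 0.0230). Phlda3, an inhibitor of Akt signalling induced by p53 (Entrez 27280, chromosome 1, 135766085 to 135769134), rose from 5.92 ± 1.15 to 13.8 ± 2.05 CPM. Higher too were Pdk4, a kinase that restrains pyruvate dehydrogenase (5.98 ± 0.641 to 18.5 ± 2.01 CPM), Errfi1, a feedback inhibitor of the epidermal growth factor receptor (18.6 ± 3.63 to 56.8 ± 5.49 CPM), and the creatine kinase gene Ckb (11.5 ± 1.89 to 32.3 ± 2.12 CPM). Fcer2a, the low-affinity IgE receptor CD23 of B cells (Entrez 14128, chromosome 8, 3680280 to 3694174), fell from 281 ± 48.8 to 133 ± 44.5 CPM. Cd55, which protects cells from complement, fell from 405.0 ± 15.6 to 203 ± 50.8 CPM, and Cmah, an enzyme of sialic acid synthesis, from 416 ± 15.1 to 199 ± 30.4 CPM. Klrd1, the natural killer (NK) cell receptor CD94, fell from 15.5 ± 2.97 to 8.24 ± 1.38 CPM, and Rasgrp1, an activator of Ras in lymphocytes, from 147 ± 15.5 to 82.3 ± 16 CPM. Gpr132, a receptor of immune cells, fell from 57.7 ± 8.36 to 18.8 ± 5.69 CPM. Lower as well were Zc3h6 (16.7 ± 2.40 to 6.94 ± 1.88 CPM), B3gnt5 (106 ± 7.56 to 56.7 ± 16.7 CPM), Chic1 (10.7 ± 1.47 to 5.97 ± 0.292 CPM) and Syt14 (5.58 ± 2.60 to 1.15 ± 0.515 CPM). In all, edgeR called 71 of 15079 genes, 20 higher and 51 lower, and 3109 had an unadjusted p under 0.05. The count rested on single libraries: it was 0 without control 1 or control 2, 1 without busulfan 3, 4 without busulfan 1, 53 without control 3 and 470 without busulfan 2. DESeq2 called 923, a stricter filter gave 128 and no filter 42. Without control 1, the library with most adipocyte transcripts, and AOS 2, that with most acinar transcripts, 0 genes were called. The count was 0 when only the 6 libraries compared were fitted, and 41 and 11 with the acinar and heat shock levels as covariates.

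**Figure D2:**
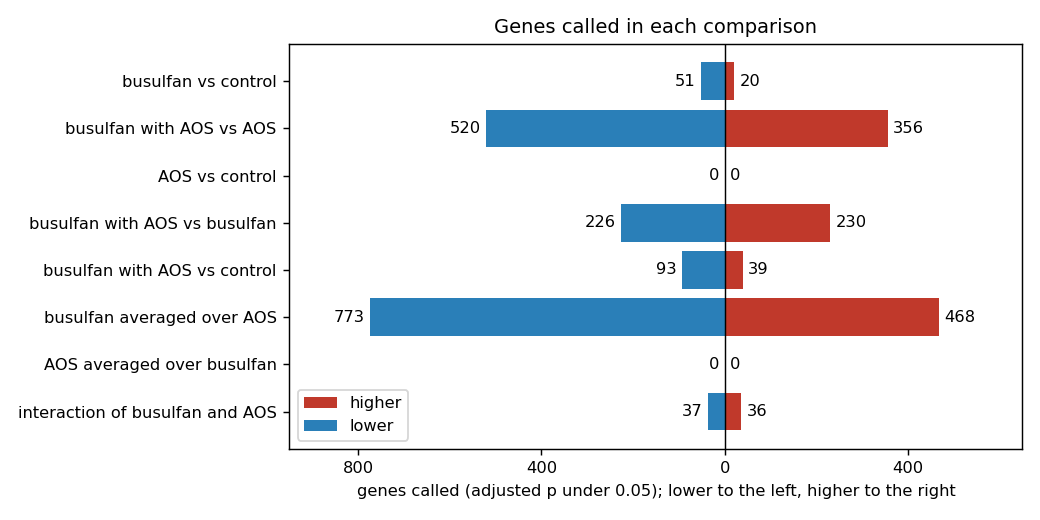
Genes called by edgeR at an adjusted p under 0.05 in each comparison (bars, number of genes, higher to the right and lower to the left). Busulfan averaged over AOS gave 468 higher and 773 lower genes, and AOS against control and AOS averaged over busulfan gave 0.

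Among the lists, neutrophil genes had the largest median log2 fold change with busulfan, 2.66, with 3 of 18 members called and 18 adjusted over the list alone (camera adjusted p = 2.58e-14, and adjusted p = 0.570 with an estimated correlation). Camp, an antimicrobial peptide of neutrophil granules, stood at 323 ± 238 CPM (SD, n = 3) in that group beside 41.9 ± 15 CPM in controls, and did not pass. The 15 B cell genes had a median of −0.41 with 1 called and 11 adjusted over the list alone (adjusted p = 0.685 with an estimated correlation). Members of that list are the transcription factor genes Ebf1 (81.4 ± 14.6 against 118 ± 16.7 CPM) and Pax5 (163 ± 28.3 against 222 ± 14.6 CPM), which did not pass over all genes. The 11 NK and cytotoxic genes had a median of −0.91 with 1 called and 9 adjusted over the list alone (adjusted p = 0.570 with an estimated correlation). Of 21 p53 targets 3 were called and 9 adjusted over the list alone, at a median of 0.19 (adjusted p = 0.0783 with an estimated correlation, and fry adjusted p = 0.000616). Also called was Aen, a nuclease induced by p53 (27.1 ± 1.40 to 37.5 ± 1.98 CPM). In the MHC class II list, median −0.42, 1 of 10 was called and 3 adjusted over the list alone (adjusted p = 0.570 with an estimated correlation). The called gene was H2-Oa, an inhibitor of peptide loading (54.4 ± 2.04 to 30.8 ± 6.53 CPM). The clock list, median −0.13, had 1 member called, the clock gene Per1 (31.2 ± 3.63 to 57.6 ± 8.52 CPM), which went against the list, and 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.570 with an estimated correlation).

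Further lists passed camera in busulfan against control with 0 members called. Mitosis (median log2 0.30), DNA replication (0.32), red pulp macrophages (0.50), haem synthesis (0.25), antioxidant genes (0.17), heat shock (0.49), basophils and mast cells (0.70) and monocytes (0.53) were higher, each with adjusted p = 0.685 with an estimated correlation. For basophils and mast cells and for monocytes, busulfan 2 lay among the controls (list levels 0.05 and −0.08, controls −0.19 to 0.07 and −0.30 to −0.05). Adjusted over the list alone, the heat shock list had 2 members called, basophils and mast cells 3, monocytes 2, and the other 5 lists 0. Plasma cells (0.34, 1 called adjusted over the list alone) were higher with adjusted p = 0.570 with an estimated correlation. T cells (−0.30) were lower, and pancreatic acinar genes (2.40) higher, each with adjusted p = 0.702 with an estimated correlation and 0 called adjusted over the list alone. Erythroid genes had a positive median of 0.28 and test but a negative mean of −0.62 (adjusted p = 0.702 with an estimated correlation, and 2 lower adjusted over the list alone). The β-globin gene Hbb-bs, which has near-identical copies, stood at 1.72 ± 0.334 CPM with busulfan and 3577 ± 5060 CPM in controls. In 7 of the 18 lists called, the levels of the 3 busulfan libraries lay apart from those of the 3 controls. These were neutrophils, NK and cytotoxic cells, red pulp macrophages, p53 targets, MHC class II, antioxidant and clock genes. The chance share of 10% holds for lists not picked on these libraries. The 18 lists were picked on them, so it is no reference here. In the other 11 the groups overlapped. Across comparisons 0 lists held with an estimated correlation, and other splits of the same 6 libraries called up to 18 lists, as the real split did.

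**Figure D3:**
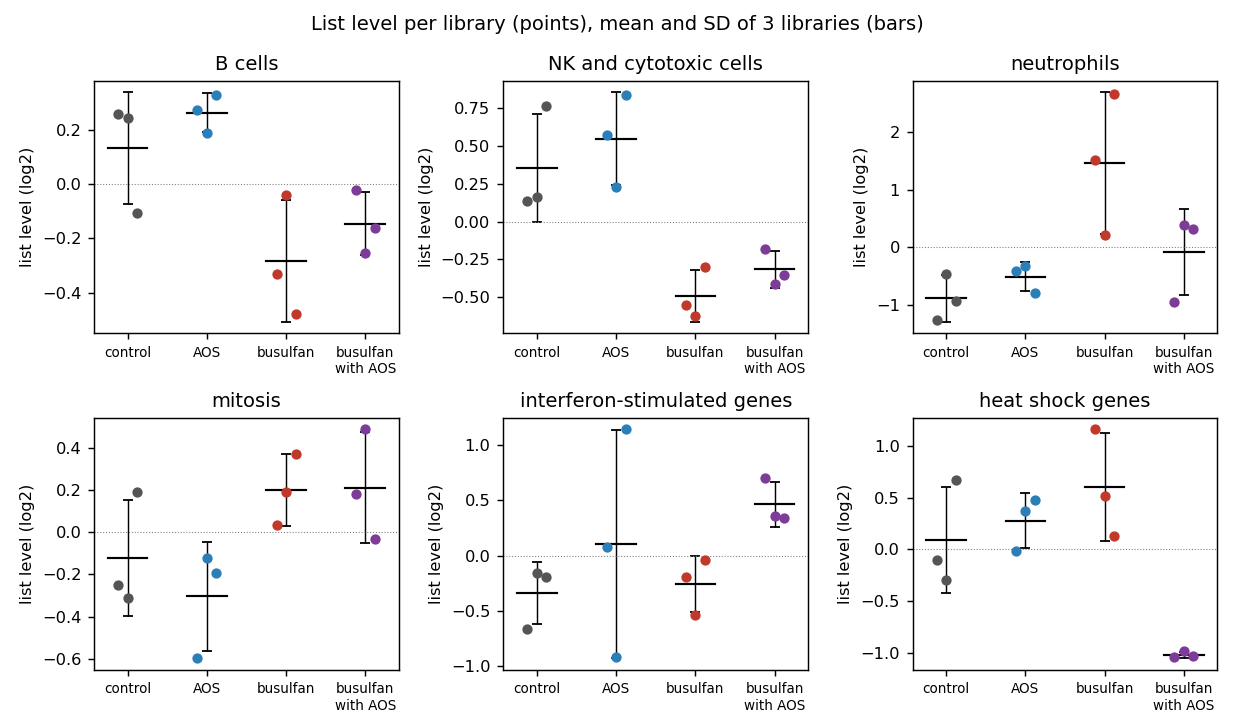
List level per library (vertical axes, log2, median over members of log2 CPM relative to the mean of all libraries) for 6 gene lists (panels) in the 4 groups (horizontal axis), with points for libraries and bars for mean and SD of 3. Heat shock genes lie near −1 in the 3 libraries of busulfan with AOS and above −0.4 in the other 9.

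Busulfan with AOS against AOS asks what busulfan changed in mice that also received AOS. Eda2r again rose, from 1.44 ± 0.314 to 5.09 ± 1.30 CPM (n = 3 each; log2 1.82 ± 0.25 SE, edgeR adjusted p = 0.00976). Tnfrsf13c, the receptor for B cell activating factor, fell from 178 ± 10.3 to 95.9 ± 15.9 CPM, and the complement receptor gene Cr2 fell from 728 ± 66.5 to 484 ± 38.9 CPM. Spib, a transcription factor of B cells, fell from 356 ± 11.4 to 242 ± 23.0 CPM. The cytotoxic genes Gzma (33.0 ± 14.4 to 10.2 ± 2.01 CPM) and Prf1 (10.3 ± 1.61 to 3.74 ± 0.894 CPM) and the NK cell receptors Ncr1 (15.3 ± 7.83 to 5.41 ± 1.13 CPM) and Klrd1 (15.9 ± 1.95 to 10.3 ± 0.285 CPM) also fell. Cdc20, an activator of the anaphase complex (52.9 ± 5.15 to 90.2 ± 13.1 CPM), and Pole, the catalytic subunit of DNA polymerase epsilon (46.5 ± 6.94 to 79.4 ± 12.7 CPM), rose. Mcm6 of the replicative helicase (217 ± 28.7 to 333 ± 34.5 CPM) and Prdm1, the plasma cell regulator Blimp-1 (10.1 ± 0.816 to 16.6 ± 0.673 CPM), rose likewise. Cd5l, a secreted protein of macrophages, rose from 38.0 ± 15.4 to 74.3 ± 14.8 CPM, and the superoxide dismutase Sod1 from 181 ± 13.7 to 229 ± 19.4 CPM. Chaperone genes that fell were Hsph1 at 370.5 ± 106 and 73.9 ± 4.94 CPM, Dnaja1 at 575 ± 89.3 and 156 ± 11.7 CPM, Hspa8 at 2963 ± 639 and 1112 ± 93.0 CPM and Dnajb1 at 184 ± 37.5 and 68.1 ± 7.47 CPM with AOS and with both. Nr1d1, a repressor in the circadian clock, rose from 5.17 ± 0.543 to 17.3 ± 3.24 CPM, and Cirbp, a cold-inducible RNA-binding protein, from 29.0 ± 8.12 to 65.3 ± 1.28 CPM.

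Other genes with the largest rises in that comparison were the signalling regulators Rgs16 (2.18 ± 0.664 to 5.68 ± 1.23 CPM) and Dgki (3.05 ± 1.24 to 7.32 ± 2.51 CPM), and the Notch effector Rbpj (16.1 ± 1.43 to 36.8 ± 11.3 CPM). Rises were also found for the inhibitor of differentiation Id1 (4.31 ± 1.09 to 9.29 ± 0.721 CPM), the glucose transporter Slc2a4 (13.7 ± 3.42 to 28.5 ± 6.62 CPM), Phyhip (17.1 ± 2.89 to 35.3 ± 6.44 CPM) and Gabra3 (0.173 ± 0.0992 to 5.58 ± 7 CPM). The liver genes Alb (80.3 ± 45.7 to 7.98 ± 2.58 CPM), Apoa2 (11.9 ± 7.68 to 0.746 ± 0.239 CPM), Ttr (8.94 ± 5.83 to 0.546 ± 0.340 CPM) and Mup7 (10.7 ± 8.25 to 0.767 ± 0.334 CPM) fell, as did Tsga13 (5.997 ± 1.86 to 1.74 ± 0.627 CPM). The AOS libraries also held the largest shares of acinar transcripts. Whether the liver transcripts came from tissue outside the spleen was not tested, so their fall need not be an effect of busulfan. The insulin gene Ins2 stood at 0.855, 49.3 and 5.51 CPM in the AOS libraries, and 1 count was found in the 3 libraries of busulfan with AOS. In all, edgeR called 876 genes, 356 higher and 520 lower, while limma-trend on FPKM gave 504 higher and 324 lower. With a library left out 122, 278 and 198 genes were called (AOS 1, 2 and 3) and 247, 28 and 241 (busulfan with AOS 1, 2 and 3), and DESeq2 called 1773. With the acinar or the heat shock level as a covariate, 0 genes were called, with 50 without control 1 and AOS 2 and 440 when only these 6 libraries were fitted. Both list levels lay apart between these groups, so the covariates take up part of the contrast whatever its cause.

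The mitosis list had a median of 0.52 with 1 of 20 members called and 18 adjusted over the list alone, and DNA replication 0.45 with 2 of 19 called and 16 adjusted over the list alone (adjusted p = 0.800 with an estimated correlation for each). B cells (median −0.41, 4 called and 10 adjusted over the list alone), NK and cytotoxic cells (−0.98, 4 and 9), antioxidant genes (0.25, 1 and 4), plasma cells (0.29, 1 and 4) and heat shock genes (−1.41, 3 and 8) passed camera likewise, with adjusted p = 0.800 with an estimated correlation. T cells (−0.30), erythroid genes (0.33), haem synthesis (0.30) and red pulp macrophages (0.24, 1 called and 1 adjusted over the list alone) passed with adjusted p = 0.847 with an estimated correlation, the first 3 with 0 members called either way. The 20 acinar genes had a median of −4.13, with 0 called and 20 adjusted over the list alone (adjusted p = 0.847 with an estimated correlation). Neutrophil genes, at a median of 0.46, did not pass camera here (adjusted p = 0.203). Of the 12 lists called, the levels overlapped between the groups in 4 (T cells, red pulp macrophages, erythroid genes and haem synthesis) and lay apart in 8.

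AOS against control asks what AOS did alone. With edgeR 0 genes were called and 894 had an unadjusted p under 0.05, limma-trend on FPKM called 0, and DESeq2 called 70. The genes with the smallest p did not pass (edgeR adjusted p = 0.449 for each). Higher values were seen for Slx4, a nuclease scaffold of crosslink repair (43.2 ± 0.474 against 34.6 ± 1.14 CPM, SD, n = 3 each) and Pdk4 (11.9 ± 3.07 against 5.98 ± 0.641 CPM). The pancreatic genes with higher values were Cela1 (638 ± 817 against 16.3 ± 3.43 CPM), Cuzd1 (29.1 ± 38.8 against 0.128 ± 0.127 CPM) and Pnliprp2 (89.3 ± 119 against 0.127 ± 0.221 CPM). Lower values were seen for Hmgn5 (27.0 ± 2.21 against 35.5 ± 0.375 CPM), the clock gene Bhlhe41 (17.8 ± 1.36 against 24.4 ± 1.68 CPM), Fam204a (19.6 ± 2.23 against 26.7 ± 0.609 CPM), Osbpl1a (14.3 ± 1.95 against 21.2 ± 1.95 CPM) and the calcium channel gene Cacna1e (0.922 ± 0.0767 against 58.6 ± 16.3 CPM). The count was 2 without AOS 2, and 1 when only these 6 libraries were fitted.

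Of the lists, 16 passed camera in AOS against control with 0 members called over all genes. Pancreatic acinar genes had the largest median, 7.82, with 20 called adjusted over the list alone (adjusted p = 0.351 with an estimated correlation). Adipocyte genes had −4.37 with 8 of 9 adjusted over the list alone (adjusted p = 0.577 with an estimated correlation), and the list level was highest in control 1, at 4.02. Germinal centre genes were higher at 0.43 (adjusted p = 0.577 with an estimated correlation), with values of Bcl6, a regulator of germinal centre B cells, of 58.6 ± 0.229 against 47.6 ± 3.97 CPM. The list level of AOS 3, −0.25, lay among the controls (−0.43 to −0.23). MHC class I genes were higher at 0.34, with 2 adjusted over the list alone (adjusted p = 0.577 with an estimated correlation). Members are H2-K1 (1085 ± 175 against 767 ± 108 CPM) and the immunoproteasome gene Psmb10 (61.2 ± 4.63 against 50.5 ± 3.02 CPM), and the list level of AOS 2, −0.13, lay among the controls (−0.28 to 0.01). Higher with adjusted p = 0.758 with an estimated correlation were interferon-stimulated genes (0.65), with AOS 2 below and AOS 3 furthest above the controls (list levels −0.92 and 1.14, controls −0.67 to −0.16), T cells (0.18, but −0.32 with the acinar level as a covariate, camera adjusted p = 0.0197), Toll-like receptor genes (0.17), NK and cytotoxic cells (0.22), B cells (0.11) and plasma cells (0.13), each with 0 adjusted over the list alone. Lower at the same adjusted p = 0.758 with an estimated correlation were mitosis (−0.22), DNA replication (−0.15), haem synthesis (−0.19) and smooth muscle (−0.26), also with 0. For the first 3 of these, AOS 1 stood below the controls (list levels −0.60, −0.52 and −0.49) and AOS 2 and AOS 3 lay among them. Stem and progenitor genes were lower at −0.22, with Kit, the stem cell factor receptor, at 32.5 ± 1.74 against 39.4 ± 8.51 CPM (adjusted p = 0.351 with an estimated correlation), and erythroid genes at −0.20 (adjusted p = 0.800 with an estimated correlation). For erythroid genes AOS 1, at a level of −0.59, stood below the controls (−0.32 to 0.31), and AOS 2 and AOS 3 lay among them (each −0.04). The levels of the groups lay apart in 3 of the 16 lists, acinar, adipocyte and stem and progenitor genes, and overlapped in 13. For stem and progenitor genes the groups nearly touched, with AOS 1 at −0.014 and control 2 at 0.001. Other splits of these 6 libraries called up to 18 lists.

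Busulfan with AOS against busulfan asks what AOS changed after the drug. Hsph1, a heat shock protein of the Hsp110 class (Entrez 15505, chromosome 5, 149616843 to 149636498), fell from 608 ± 360.0 to 73.9 ± 4.94 CPM (n = 3 each; log2 −3.04 ± 0.46 SE, edgeR adjusted p = 0.0115). Hspb1, a small heat shock protein, fell from 20.9 ± 9.35 to 4.57 ± 0.607 CPM, and the Hsp40 gene Dnaja1 from 670 ± 296 to 156 ± 11.7 CPM. Also lower were Hspa8, the constitutive Hsp70 (3194 ± 875 to 1112 ± 93.0 CPM), Hspe1 (196 ± 56.6 to 105 ± 6.65 CPM) and Ahsa2, an Hsp90 cofactor (189 ± 99.3 to 52.2 ± 2.91 CPM). Hspa1a and Hspa1b, inducible Hsp70 genes of near-identical sequence, had 0 and 2 counts in the 3 libraries of busulfan with AOS. Cirbp, which is induced by cold (Entrez 12696, chromosome 10, 80165990 to 80172786), moved the other way, from 22.04 ± 2.61 to 65.3 ± 1.28 CPM (log2 1.57 ± 0.21 SE, edgeR adjusted p = 0.00824). The clock genes Nr1d1 (6.40 ± 2.32 to 17.3 ± 3.24 CPM) and Dbp (4.47 ± 1.57 to 11.4 ± 2.22 CPM) rose. Errfi1 fell from 56.8 ± 5.49 to 16.6 ± 4.21 CPM and the arginase gene Arg2 from 7.12 ± 2.26 to 1.68 ± 0.310 CPM. The inositol transporter gene Slc5a3 fell from 34.2 ± 16.5 to 9.12 ± 0.538 CPM, Ly6k from 5.10 ± 2.49 to 1.09 ± 0.421 CPM and the mast cell and basophil protease Prss34 from 12.9 ± 12.4 to 2.01 ± 0.886 CPM. Zc3h6 (6.94 ± 1.88 to 19.2 ± 1.07 CPM), the interferon-induced Ifit1bl1 (8.27 ± 0.290 to 22.4 ± 4.83 CPM) and Stoml1 (18.6 ± 2.49 to 39.2 ± 3.80 CPM) rose. So did Rpain (1.96 ± 0.873 to 5.08 ± 0.588 CPM) and Gabra3 (0.212 ± 0.0734 to 5.58 ± 7 CPM). Hbb-bs, which has near-identical copies, stood at 1.72 ± 0.334 CPM with busulfan and 5551 ± 7790 CPM with both. It varied widely within groups, from 841 to 14500 CPM with both and from 26.8 to 9370 CPM in controls. The share of all haemoglobin transcripts did not rise, at 8.69 ± 0.289% with busulfan and 8.01 ± 1.90% with both. Tapbp had 3 counts in the libraries of busulfan with AOS beside 20.9 ± 31.7 CPM with busulfan.

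**Figure D4:**
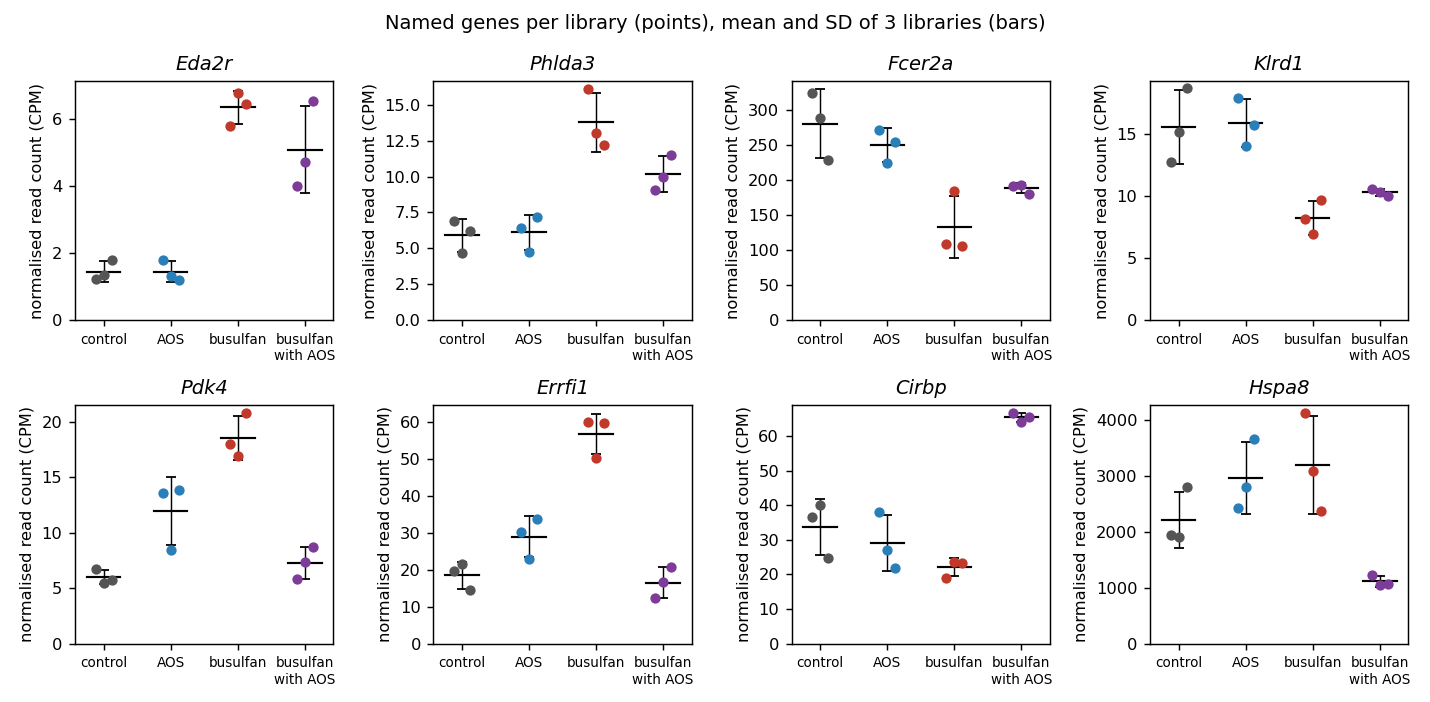
Normalised read count (vertical axes, CPM, linear from 0) of 8 named genes (panels) in each library (points) of the 4 groups (horizontal axis), with bars for mean and SD of 3 libraries. Eda2r rose with busulfan to 6.36 CPM alone and 5.09 CPM with AOS, and Cirbp reached 65.3 CPM with busulfan and AOS.

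In this comparison edgeR called 456 genes, 230 higher and 226 lower, against 221 higher and 135 lower with limma-trend on FPKM. With a library left out 72, 531 and 286 genes were called (busulfan 1, 2 and 3) and 45, 83 and 70 (busulfan with AOS 1, 2 and 3). DESeq2 called 1157, and 86 were called when only these 6 libraries were fitted and 0 with the heat shock level as a covariate. The heat shock list level was −1.04 to −0.98 with both treatments and −0.30 or more in all other libraries. This covariate therefore takes up much of the contrast whatever its cause. The heat shock list had a median of −1.67, unchanged with Hspa1a and Hspa1b set to the limit of 3 counts, with 6 of 9 called and 9 adjusted over the list alone (camera adjusted p = 5.25e-10, adjusted p = 0.591 with an estimated correlation, and fry adjusted p = 0.0318). Neutrophil genes had a median of −1.77 with 0 of 18 called and 17 adjusted over the list alone (adjusted p = 0.962 with an estimated correlation), with Prtn3, a granule protease, at 14.4 ± 4.83 against 61.5 ± 45.9 CPM. The neutrophil level of busulfan 2, 0.21, lay among those of busulfan with AOS (−0.94 to 0.40). Basophil and mast cell genes had −1.30 with 1 called and 5 adjusted over the list alone (adjusted p = 0.591 with an estimated correlation), and busulfan 2, at a level of 0.05, again lay among those of busulfan with AOS (−0.54 to 0.06). Interferon-stimulated genes had 0.67 (adjusted p = 0.962 with an estimated correlation), with the antiviral genes Ifit3 at 71.2 ± 14.3 against 23.6 ± 5.24 CPM and Mx1 at 32.3 ± 10.7 against 12.7 ± 1.82 CPM. Acinar genes had 1.29 (adjusted p = 0.962 with an estimated correlation), and both lists had 0 called either way. Other splits of these 6 libraries called up to 15 lists, where the real split called 5.

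Busulfan with AOS against control compares the spleen after both treatments with the untreated one. Nr1d1 rose from 4.34 ± 0.381 to 17.3 ± 3.24 CPM (n = 3 each; log2 2.00 ± 0.25 SE, edgeR adjusted p = 0.0151) and Eda2r from 1.45 ± 0.304 to 5.09 ± 1.30 CPM. Also higher were Il12b, a subunit of interleukin-12 (1.83 ± 0.0398 to 5.45 ± 0.452 CPM), Cd5l (28.4 ± 4.29 to 74.3 ± 14.8 CPM) and Prdm1 (9.13 ± 0.828 to 16.6 ± 0.673 CPM). Others were the T cell chemokine receptor Cxcr3 (10.9 ± 0.660 to 17.4 ± 1.29 CPM), Fscn1, an actin-bundling protein of mature dendritic cells (31.8 ± 2.88 to 52.4 ± 3.50 CPM), and Zbtb32 (4.30 ± 0.250 to 8.51 ± 2.25 CPM). Id1 (4.02 ± 1.06 to 9.29 ± 0.721 CPM) and Klf11 (18.8 ± 2.90 to 29.4 ± 0.728 CPM) rose too. Cd209d, a lectin receptor of the SIGN family, fell from 6.96 ± 1.27 to 2.26 ± 0.541 CPM, Dnaja1 from 472 ± 132 to 156 ± 11.7 CPM, and the growth-restraining gene Tob1 from 30.6 ± 1.53 to 15.8 ± 2.65 CPM. Gpr171 (50.3 ± 3.18 to 25.6 ± 3.81 CPM), Ccdc117 (105 ± 28.0 to 40.9 ± 2.62 CPM) and Acrbp (17.5 ± 0.310 to 8.55 ± 1.45 CPM) fell as well. So did Nat14 (6.09 ± 0.398 to 2.94 ± 0.0123 CPM), Cdh24 (5.02 ± 0.361 to 2.56 ± 0.346 CPM), Lrrc10 (19.2 ± 1.63 to 9.86 ± 1.36 CPM) and Abhd16a (28.4 ± 4.41 to 15.1 ± 2.12 CPM). In all 132 genes were called by edgeR, 39 higher and 93 lower, and 760 by DESeq2. Left-out libraries gave 9, 3 and 30 genes (control 1, 2 and 3) and 5, 8 and 7 (busulfan with AOS 1, 2 and 3), only these 6 libraries gave 1, the heat shock covariate 2, and 0 genes were called without both control 1 and AOS 2.

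Of the lists, 16 passed camera in that comparison. Plasma cells (median 0.30, 1 called and 3 adjusted over the list alone) and p53 targets (0.11, 1 called, and 4 higher and 1 lower adjusted over the list alone) had adjusted p = 0.518 with an estimated correlation and passed fry (adjusted p = 0.0217 for each). Neutrophil genes were higher at 0.94 (adjusted p = 0.714 with an estimated correlation), with library 1 of busulfan with AOS, at a level of −0.94, among the controls (−1.25 to −0.45) and libraries 2 and 3 above them (0.40 and 0.32). The other 13 had adjusted p = 0.663 with an estimated correlation. Higher among them were germinal centre (0.57), regulatory T cells (0.41), red pulp macrophages (0.44), mitosis (0.32), DNA replication (0.29), crosslink repair (0.25), interferon-stimulated genes (0.86), antioxidant genes (0.18) and acinar genes (3.72), and lower were B cells (−0.31), NK and cytotoxic cells (−1.02), adipocytes (−2.76) and heat shock genes (−0.995). Regulatory T cell genes had 3 called adjusted over the list alone, and the checkpoint receptor Ctla4 of that list stood at 12.5 ± 2.56 against 7.07 ± 0.771 CPM. The list level of library 2 of busulfan with AOS, −0.12, lay among the controls (−0.23 to −0.11), and those of libraries 1 and 3 above them (0.40 and 0.39). The adipocyte level was highest in control 1, at 4.02, and library 3 of busulfan with AOS, at 0.77, lay above controls 2 and 3 (0.52 and 0.16). Called adjusted over the list alone, red pulp macrophages had 2, heat shock genes 7, NK and cytotoxic cells 4, and germinal centre and B cells 1 each. The levels of the groups lay apart in 8 of the 16 lists and overlapped in B cells, regulatory T cells, neutrophils, red pulp macrophages, mitosis, DNA replication, acinar genes and adipocytes. Library 3 of busulfan with AOS and control 3 nearly touched in antioxidant genes (0.036 and 0.033) and germinal centre genes (−0.205 and −0.229). Other splits of these 6 libraries called up to 16 lists.

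Averaged over AOS, busulfan raised 468 genes and lowered 773 (1241 called by edgeR, 2375 by DESeq2). Among list members, 12 of 18 neutrophil genes rose (17 adjusted over the list alone, median log2 1.65). In mice that also received AOS the neutrophil median was 0.46, with 0 members called (camera adjusted p = 0.203). Of 15 B cell genes 11 fell (14 adjusted over the list alone, median −0.40), and 8 of 11 NK and cytotoxic genes fell (9, −1.13). In DNA replication 7 of 19 rose (19, 0.38), in mitosis 3 of 20 (20, 0.40), among p53 targets 5 of 21 (8 higher and 1 lower, 0.12, and −0.03 in mice that also received AOS) and in the plasma cell list 3 of 10 (6, 0.29), while 2 of 10 MHC class II genes fell (5, −0.33). Lists with camera calls included these 8 and T cells, red pulp macrophages, haem synthesis, antioxidant genes, crosslink repair and erythroid genes (median 0.31, mean −0.16, test higher). Their adjusted p = 0.367 to 0.721 with an estimated correlation, and 7 of the 14 passed fry. The count of genes ran from 83 without library 2 of busulfan with AOS to 2054 without control 3, and was 231, 143, 232, 644 and 659 without control 1, control 2, AOS 1, AOS 2 and AOS 3. It was 814 and 285 without busulfan 1 and 3, 717 and 630 without libraries 1 and 3 of busulfan with AOS, 474 and 41 with the acinar and heat shock covariates, and 9 without control 1 and AOS 2.

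Averaged over busulfan, AOS changed 0 genes by edgeR, with 1818 at an unadjusted p under 0.05, 231 called by DESeq2 and 1 by limma-trend on FPKM. Leaving out control 1, AOS 2, busulfan 1 or busulfan 2 gave 1, 2, 1 and 4 genes, and leaving out any other library gave 0. Of the lists 19 passed camera, at adjusted p = 0.552 to 0.697 with an estimated correlation. Acinar genes (median 4.51, 20 adjusted over the list alone) and interferon-stimulated genes (0.69, 3 adjusted over the list alone) were higher. Lower were heat shock genes (−0.87, 9 adjusted over the list alone), neutrophils (−0.64), basophils and mast cells (−0.85), adipocytes (−2.46), glutathione S-transferases (−0.16), megakaryocytes and platelets (−0.16) and smooth muscle (−0.38). For the first 2 of these the medians after busulfan were −1.67 and −1.77. With AOS alone heat shock genes had a median of 0.02 (camera adjusted p = 0.583) and neutrophils 0.33 (camera adjusted p = 0.0586). The interaction of both lists passed camera, but had adjusted p = 0.988 with an estimated correlation. MHC class I genes had a positive median of 0.29 and test but a negative mean of −0.08, and erythroid genes a negative median of −0.17 and test but a positive mean of 0.30. The erythroid median was 0.09 with the heat shock level as a covariate. Adjusted over the list alone, 8 adipocyte genes and 2 basophil and mast cell genes were lower, 1 plasma cell and 1 erythroid gene higher, and 4 MHC class I genes higher and 2 lower. Also among the 19 were B cells (0.16), T cells (0.25), regulatory T cells (0.24), germinal centre (0.33), plasma cells (0.10) and MHC class II genes (0.21) as higher, and haem synthesis (−0.17) and DNA replication (−0.08) as lower.

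The interaction asks whether the effect of AOS differed with and without busulfan. It was called for 73 genes by edgeR, 36 positive and 37 negative, against 87 and 37 with limma-trend on FPKM and 629 genes with DESeq2. Errfi1 had an interaction of −2.42 on the log2 scale, Pdk4 −2.34, Zc3h6 2.18 and Cirbp 1.78. Of the lists 4 passed camera, all negative. Neutrophil genes had a median of −1.94 (0 called, 16 adjusted over the list alone), acinar genes −6.48 (0 and 19) and heat shock genes −1.94 (3 and 7), each with adjusted p = 0.988 with an estimated correlation. The p53 targets had −0.31 (0 called, 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.772 with an estimated correlation). Without a library the count ran from 8 (library 2 of busulfan with AOS) to 110 (busulfan 3). It was 26, 19 and 35 without control 1, 2 and 3, 26, 21 and 22 without AOS 1, 2 and 3, 18 without busulfan 1, and 15 and 27 without libraries 1 and 3 of busulfan with AOS. It was 1 and 0 with the acinar and heat shock covariates and 7 without control 1 and AOS 2.

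Comparisons that share no library were set beside each other across genes, which are not independent replicates. The simulations drew each gene independently of the others, so their spread may be too narrow as a reference. The log2 fold changes of busulfan with and without AOS had r = 0.113 (simulated with no effect 0.00657 ± 0.0494, covariance 0.0423 against 0.000997), and 57 of the 71 genes called in busulfan against control had the same sign with AOS. There 11 genes were lower in both (1.76 expected for independent lists) and 1 was higher in both (0.472 expected), while 2 were higher and then lower (0.690 expected) and 3 lower and then higher (1.2 expected). The changes of AOS with and without busulfan had r = 0.0733 (simulated 0.00770 ± 0.0375, covariance 0.0263 against 0.00114). Leaving out control 2 turned the first r to −0.0323, and leaving out library 1 of busulfan with AOS turned the other to −0.0390.

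Of the 71 genes called in busulfan against control, 21 were called in the opposite direction in busulfan with AOS against busulfan. Of these, 15 were lower and then higher (0.778 expected for independent lists) and 6 were higher and then lower (0.300 expected). The lists share the busulfan libraries and are not independent, so these expected numbers are not the values without an effect. The lower ones include Zc3h6 (log2 −1.27 then 1.46), Cmah (−1.06 then 0.69), B3gnt5 (−0.91 then 0.95) and H2-Oa (−0.82 then 0.64), and, chosen after their values were seen, the kinase gene Ttbk1 (−1.71 then 1.42) and the peptidase gene Dpp4 (−0.46 then 0.42). The higher ones are Pdk4 (1.63 then −1.34), Errfi1 (1.61 then −1.77) and Per1 (0.88 then −1.01), and, chosen in the same way, the stress-induced Ddit4 (1.01 then −1.40), the GTPase gene Rhob (0.69 then −0.46) and Sap30 (0.51 then −0.43). Both comparisons hold the same busulfan libraries with opposite sign. Simulations with no effect, with each gene drawn independently, gave r = −0.500 ± 0.0236, and the observed r was −0.383. The covariance was −0.131, against −0.0702 simulated, a difference of −0.0612, and part of any excess may come from the shared libraries, since 3 libraries cannot be divided evenly. The count was 0 without control 1 or control 2, 3 without busulfan 1, 196 without busulfan 2, 1 without busulfan 3, and 7, 11 and 8 without libraries 1, 2 and 3 of busulfan with AOS. It was 0 with the heat shock covariate and 8 with the acinar covariate.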

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

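The tests of explanations for the heat shock, acinar and granulocyte transcripts were chosen after the result they address was seen, while the splits of the libraries were chosen before. The results below were taken up because genes were called in edgeR's interaction test, which called 73, or because lists passed camera for the interaction. The acinar and neutrophil lists entered through camera only, with 0 members called by edgeR. On the log2 scale the interaction was −3.33 for the chaperone gene Hsph1, −2.39 for Dnaja1, −2.37 for Hspb1 and −1.94 for Hspa8. It was −2.42 for Errfi1, −2.34 for Pdk4, −1.37 for Per1, −1.58 for Gpr171, −1.39 for Cdh24 and −1.03 for Acrbp. Positive values were 2.18 for Zc3h6, 1.78 for Cirbp, 1.12 for Stoml1, 1.09 for Fam204a and 0.97 for Bhlhe41. Among lists passing camera the median was −1.94 for heat shock genes, −6.48 for pancreatic acinar genes, −1.94 for neutrophils and −0.31 for p53 targets, and 0 of these lists held with an estimated correlation.

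Heat shock genes were lower in the 3 libraries of busulfan with AOS than in the other 9, while the cold-induced genes Cirbp (log2 1.57, edgeR adjusted p = 0.00824) and Rbm3 (0.58, edgeR adjusted p = 0.0482) were higher than with busulfan alone. Against AOS edgeR adjusted p = 0.0166 for Cirbp and 0.0663 for Rbm3, and against control 0.0573 and 0.242. A return by AOS to the control level is argued against, since the list level lay below control by a log2 of −1.11 with an interval half-width of 0.73. The light-phase clock genes rose relative to the opposite arm by 0.79 with a half-width of 0.28. The rise was 0.62 against AOS and 0.44 against control. These arms hold 6 and 3 genes and were chosen after the heat shock result was seen. The light-phase arm holds Nr1d1 and Dbp, already named above for their rise, and leaves out Per1. The rise therefore cannot decide whether a different hour of sampling contributed, which stays open. The whole clock list of 14 did not pass against busulfan, with 8 higher and 6 lower (camera adjusted p = 0.577). The clock gene Per1 was called lower there (log2 −1.01, edgeR adjusted p = 0.00824). An effect of the treatments on the clock stays open too, as hour and handling are not given in the sources used here and would be confounded with group, while lower glucocorticoid signalling cannot be told apart, at −0.14 with a half-width of 0.16 over 9 other target genes, of which 6 had lower values and 1 was called.

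Pancreatic acinar transcripts were high in the 3 AOS libraries. Pancreas tissue in the samples, which lies beside the spleen, could account for this, since 3 of 4 islet hormone genes, which acinar cells do not make, lay above every control library in all 3. These were Ins1 and Ins2, with at least 10 and 13 counts and 0 in the controls, and Gcg, which rests on 1 count in an AOS library beside 1 count in a control, while Iapp had 0 counts in an AOS library. Acinar transcripts also occurred without Ins2. Library 1 of busulfan with AOS had an acinar share of 0.241% and busulfan 1 of 0.0959%, each with 0 CPM of Ins2. AOS 1 had 0.292% and 0.855 CPM. A rise of these transcripts by AOS with or without busulfan cannot be told apart, because the rise after busulfan differed from the rise with AOS alone by −6.26 with a half-width of 6.32. Why the share differed between groups was not tested.

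Granulocyte transcripts were higher with busulfan than in control. Mature blood cells left in the spleen are argued against as the only source, as Mpo, Elane, Prtn3 and Ctsg, the 4 members of the list made in early granulocyte precursors, had a median log2 fold change of 2.22 and each exceeded 2 SE, although none passed in edgeR (adjusted p = 0.0724 to 0.0886). A rise in 1 busulfan library alone is argued against too, since the list median was 2.79, 3.07 and 1.84 without busulfan 1, 2 and 3. Whether busulfan raised these transcripts with or without AOS cannot be told apart, at a difference of −1.91 with a half-width of 2.01.

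Other splits of the libraries were tested in the same way as the groups, and the numbers of splits below count the real one. For the 5 comparisons of 2 groups the 10 splits of 6 libraries are too few for a share under 0.05. In genes the real split and the highest other gave 71 and 0 for busulfan against control, 876 and 2 for busulfan with AOS against AOS, 0 and 2 for AOS against control, 456 and 3 for busulfan with AOS against busulfan, and 132 and 1 for busulfan with AOS against control. At least as many genes were called in 1, 1, 10, 1 and 1 of the 10 splits. In lists the values were 18 and 18, 12 and 19, 16 and 18, 5 and 15, and 16 and 16, with at least as many in 2, 4, 2, 10 and 2 splits. For the averages and the interaction 100 splits were made. Busulfan averaged over AOS gave 1241 genes, the highest other 215, and 1 split at least as many. AOS averaged over busulfan gave 0 against 305, and 100 splits at least as many. The interaction gave 73 against 43, and 1 split at least as many. In lists, chance may account for the calls, with at least as many in 36, 5 and 97 splits and highest other values of 22, 21 and 20 against 14, 19 and 4.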

How the results depend on the processing

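The covariates, limma-trend on FPKM, the removal of control 1 and AOS 2, and the replicate block for the agreement and reversal of comparisons were chosen after seeing the data. Precision is limited by 3 libraries per group and totals of 15051300 to 16241884 counts, at which a count of 0 allows up to 0.185 to 0.199 CPM. DESeq2 size factors kept all counts of calls within 1.5 times. Genes kept direction and side of the threshold in 922 of the values under alternatives, with 769 weaker, 10 stronger and 2 reversed, and lists in 1282, with 389 weaker and 2 reversed. The cause was not tested, except where fewer genes or libraries were used. Alternatives for normalized values alone (a pseudocount, array weights and quantile normalization) were not run. Removal of control 1 and AOS 2 gives no value for busulfan with AOS against busulfan, which holds neither.

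In the order busulfan against control, busulfan with AOS against AOS, AOS against control, busulfan with AOS against busulfan, busulfan with AOS against control, busulfan averaged, AOS averaged and interaction, edgeR called 71, 876, 0, 456, 132, 1241, 0 and 73 genes. DESeq2's Wald test called 923, 1773, 70, 1157, 760, 2375, 231 and 629. With a log2 fold change of at least 1 as well, the counts were 20, 118, 0, 99, 31, 140, 0 and 33. Without a filter busulfan against control gave 42 and the interaction 43, and with a stricter filter 128 and 115, with 40 genes called in opposite directions instead of 21. Fitting only the libraries compared gave 0, 440, 1, 86 and 1. With limma-trend on FPKM AOS averaged gave 1 and the interaction 124. The acinar covariate gave 41 for busulfan against control, 0 for busulfan with AOS against AOS, 474 for busulfan averaged, 1 for the interaction and 8 opposite calls. The heat shock covariate gave 11, 0, 0 (AOS against control), 0, 2, 41, 2 and 0, and 0 opposite calls. Both covariates overlap with the groups. The heat shock list level was −1.04 to −0.98 with busulfan and AOS and −0.30 or more elsewhere. The acinar list level was 2.97 to 6.79 with AOS alone and 2.81 or less elsewhere. Lower counts and reversed values with these covariates therefore do not show their cause. Without control 1 and AOS 2 the counts were 0, 50, 2, then 0 for busulfan with AOS against control, 9, 4 and 7.

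Leaving out 1 library gave 0 to 470 genes for busulfan against control, 28 to 278, 0 to 2, 45 to 531 and 3 to 30 for the next 4 comparisons, 83 to 2054 and 0 to 4 for the averages and 8 to 110 for the interaction. The agreement of busulfan with and without AOS (r = 0.113) ran from −0.0323 to 0.241 and reversed to −0.00231 with the acinar covariate. The AOS pair (0.0733) ran from −0.0390 to 0.2005 and was 0.198 and 0.320 with the acinar and heat shock covariates. The reversal (−0.383) ran from −0.470 to −0.319, with 0 to 196 opposite calls, and was −0.256 and −0.227 with these covariates. Reversed values were −0.32 for T cells in AOS against control (acinar), and with the heat shock covariate 0.0898 for erythroid genes in AOS averaged, 1.78 for Ins2 in busulfan with AOS against AOS and 0.18 for Ahsa2 in busulfan with AOS against busulfan.

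The replicate numbers were not taken to pair the libraries: of 18 correlations between libraries of the same number, from −0.0747 to 0.273, 5 were over 0.1, and 5 of 12 libraries were closest to their own number. Correlations between libraries of different numbers ran from −0.291 to 0.207, so a shared block is not excluded. With the replicate number as a block, edgeR called 10 genes for busulfan against control, 1 for AOS against control and 33 for the interaction, with 7 opposite calls, and the block changed no other count by over 1.5 times.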

Other observations

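The test of neighbouring genes below was chosen after the data were seen. The lists that passed camera in no comparison were Y-linked genes (lowest camera adjusted p = 0.104), dendritic cells (0.449), endothelium (0.222), extracellular matrix and fibroblasts (0.0732), immediate early genes (0.0608), inflammatory cytokines (0.0998), lymphoid stroma (0.279) and mesothelium (0.203). Their medians over comparisons lay between −0.90 and 0.52.

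Several genes had counts in some libraries and few or none in others. As the counting program is not given, reads split or shared between genes cannot be told apart from a true absence. Cacna1e, a calcium channel gene, stood at 48.7 to 77.4 CPM in the controls, 0.861 to 1.01 CPM with AOS, 3.00, 29.4 and 29.4 CPM with busulfan, and 1.2, 3.58 and 38.3 CPM with both. Trim25, an antiviral ubiquitin ligase, stood at 69.2, 6.62 and 111 CPM in the AOS libraries, 0.638 to 1.28 CPM in the controls, 1.02, 58.2 and 5.32 CPM with busulfan, and 71.5, 57.9 and 6.84 CPM with both. The complement gene C2 was found in 4 libraries, at 9.80, 6.02, 18.9 and 9.22 CPM, and had no count in the other 8. Of 14 genes present in some libraries and nearly absent in others, 11 differed within a group. Inherited differences between mice could link neighbouring genes, but the 1 neighbouring pair with the same libraries (mean 0.075 and highest 1 in 200 shuffles) was Hspa1a and Hspa1b. These near-identical genes were nearly absent from the whole group of busulfan with AOS, and 0 neighbouring pairs differed within a group, so inherited differences were left open. That this pair says nothing on inheritance was seen after the test was run.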
